A study of Mus musculus with 2 samples.

How the data were processed

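Total RNA from hippocampus of female B6CASTF1/J mice, 10 days old, was sequenced by the submitting laboratory. The labels give ribosomal RNA reduced, stranded libraries with ERCC spike-ins, 300 ng of input and 3 mice per pool, extracted with a column kit for animal tissue. The 2 libraries are biological replicates 1 and 2 of 1 group, made from differently numbered animals. No condition, age or sex differed between them, so the comparisons were levels within the tissue and replicate 2 against replicate 1.

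Each library had a gene table and a transcript table estimated from alignments to the transcriptome, called the alignment-based table, and a transcript table estimated from the reads and an index, called the read-based table. The submitters' processing notes name mouse build mm10 and annotation M21 for all of them. The programs and versions are not given in the sources used here, and the column layouts are those of RSEM and of kallisto. Expected counts, per the file headers, are estimated reads per gene or transcript with no normalization. Estimated counts of the read-based table, per the file headers, are of the same kind. TPM, per the file headers, is transcript abundance scaled to a fixed total over all entries, spike-ins included. FPKM, per the file headers, is corrected for effective length and for the number of reads, and was used in 1 alternative. The deposited percent of each gene's transcripts was read but not used, and transcript shares were computed from TPM. Use of strand in counting is not given in the sources used here, so antisense and overlapping genes are reported as uncertain.

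The alignment-based tables summed to 29858328 and 32275110 expected counts, of which 29756524 and 32148302 fell in annotated genes. Spike-ins took 0.341% and 0.393%, and phiX 1 and 2 counts. The read-based tables summed to 31027182 and 33294709. A further 26248 numbered entries held 3 and 4 counts and were left out. All 55536 Ensembl gene identifiers matched GENCODE M21, which gave gene classes and coordinates. Of 384 entries of the preset lists, 377 matched a gene and 7 did not. These were Hbb-b1, Hbb-b2, Ahsp, Rn7sl1, Rn7sl2, Rpprh1 and Cdr1os, and 1 matched through a synonym. For the read-based table, transcript values were summed per gene, and 86 genes had no entry there. Signal tracks, alignments and allele-specific values were not analysed here.

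Lists of marker and functional genes, gene pairs, isoform genes, tests and the rule for named genes were fixed before the data were examined. Named genes were the 20 nuclear protein-coding and 10 other nuclear genes with the highest mean TPM, up to 4 members of each list with the highest mean TPM, and all genes of the pairs, the isoform list and the sex-linked list. Of the genes called different between the libraries, the 10 with the largest log2 ratio in each direction at a mean TPM of 5 or more were named. Not all genes that the rule selects are described in the text, though all enter the counts and medians. Genes outside this rule are said to be chosen after their values were seen.

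Detection meant a TPM of 1 or more. Gene pairs were log2 ratios of TPM plus 0.1 within a library, called where both libraries had the same sign and the mean exceeded 2 SD. Replicate 2 was compared with replicate 1 per gene by an exact two-sided conditional binomial test on rounded expected counts, with the probability set by TMM effective library sizes. Genes with 10 or more counts summed over both libraries were tested, with Benjamini-Hochberg adjustment and calls at an adjusted p of 0.05 and a log2 ratio of 1 or more. Ratios used a pseudocount of 0.5 counts. A gene at 0 in a library was bounded with a floor of 3 counts in that library. The common biological coefficient of variation came from an intercept-only fit of edgeR after its own filter. List medians were set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries with no p. Gene classes were compared among genes with 200 or more counts. Retained-intron and coding transcripts were compared within genes with 50 or more counts, with 1000 bootstrap draws. The leading transcript was taken for genes at a TPM of 5 or more, and shares of genes have Wilson intervals at 95% confidence. For the 9535 genes compared between the tables of replicate 1, the interval was 74.6% to 76.3%.

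The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The scripts were tested on simulated data. In counts drawn from the real means and library sizes with 200 changed genes among 20566 tested, the library test called 98 of 100 genes changed 4-fold and 97 of 100 changed 2.83-fold, and 0 unchanged genes. With 18386 genes, a coefficient of variation of 0.1 was estimated as 0.0992 and a library ratio of 1.25 as 1.25. A simulated log2 shift of 1 placed the astrocyte list at the 100 percentile, and no shift placed it at 92.9.

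Alternatives were the read-based table, DESeq2 size factors, total counts and spike-in counts as scaling, other count and TPM minimums, other pseudocounts, other ratio thresholds, protein-coding genes alone, FPKM for the pairs, and leaving out each library in turn. A count of genes called in both tables was added after the data were examined.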

Results

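Total RNA was sequenced from the hippocampus of female B6CASTF1/J mice, hybrids of a laboratory and a wild-derived parent strain, at 10 days of age. The 2 libraries formed 1 group as biological replicates 1 and 2. Each was made from 300 ng of RNA from a pool of 3 females, and the label names a layer of the hippocampus without saying which. The libraries were ribosomal RNA reduced and held ERCC spike-ins, synthetic RNAs of known sequence added to the sample. Replicate 1 held 29858328 expected counts and replicate 2 held 32275110. The series held no second condition, so levels were described within the tissue and the replicates were set against each other. Levels are TPM, transcript abundance corrected for length and depth, from the alignment-based table and are given as mean ± SD (n = 2) or as replicate 1 and replicate 2. Coordinates are those of mouse build mm10.

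The first question was which RNAs the tissue contained. Actin, tubulin and translation genes were among the most abundant protein-coding transcripts, while small structural RNAs took a large part of the molecules. Nuclear protein-coding genes held 79.4% of the expected counts and 44.8 ± 0.461% of the TPM. Short and structural RNAs held 5.18 ± 0.231% of the counts but 38.1 ± 1.13% of the TPM, since TPM divides by length. In the read-based table the same class held 0.465% of the TPM and protein-coding genes held 75.1%. Mitochondrial ribosomal RNA made up 7.23 ± 0.375% of the TPM, mitochondrial messenger RNAs 2.14 ± 0.206% and long non-coding RNAs 4.13%. Of 22015 annotated nuclear protein-coding genes, 13019 reached a TPM of 1 in both libraries, 7995 reached 10 and 793 reached 100. Among 13374 long non-coding genes, 1124 reached a TPM of 1 in both. At these depths a gene with 0 counts could have held up to 3 counts. Intervals and limits of this kind cover counting error alone.

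The most abundant nuclear protein-coding transcript was Actb, cytoplasmic beta-actin (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754), at a TPM of 1944 ± 168. It was followed by the translation elongation factor Eef1a1 at 1769.8 ± 21.3 and by Tuba1a, an alpha-tubulin of growing neurons, at 1527 ± 198. Next came Cpe, an enzyme that trims neuropeptide precursors, at 1179.6 ± 145 and the lipid carrier Apoe, made largely by astrocytes, at 1126 ± 4.70. Others among the leading 20 were Rpl41, Actg1, Calm3, Cst3, Tubb2a, Tmsb4x, Fth1, Ppia, Gnas, Calm2, Cfl1, Atp5b and Snurf. They ran from 1099 ± 13.2 for Rpl41 down to 742 ± 10.4 for Snurf. Eef1a1, Ppia and Rpl41 have processed copies in the genome, and Snurf overlaps Snrpn and had 0 counts in the read-based table, so their levels are uncertain.

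Among other nuclear genes, Rn7s1 and Rn7s2, the RNA of the signal recognition particle, were listed at an identical 133314 ± 6454. They are near-identical copies, so the split between them is uncertain. Rn7sk, which restrains transcription elongation (chromosome 9, 78175303 to 78175633), stood at 63885 ± 191, and Rpph1, the RNA of ribonuclease P, at 9076 ± 449. Rmrp, the RNA of ribonuclease MRP, had overlapping entries at 4215 ± 529 and 4097 ± 333. Gm26917 stood at 18612 ± 2144 and Gm42418 at 4042 ± 609, side by side on chromosome 17. Both are annotated as long non-coding RNAs and enter the share of that class, and the source of their reads was not examined, so they are uncertain. Gm28661 at 5942 ± 5.57 and Gm10925 at 4202 ± 383 lie on chromosome 1 in what is known as a nuclear copy of mitochondrial DNA, and no sequence match was made here, so mitochondrial reads may be counted there. Levels of the short RNAs held for the alignment-based table alone. In the read-based table Rn7sk stood at a TPM of 19.1 and 284, and Rpph1 at 6.49 and 6058.

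The second question was which cell types the tissue contained. Markers of every hippocampal field, of interneurons and of each glial class were present. Astrocyte and glutamatergic neuron markers were the highest of the cell type lists in the alignment-based table with all members counted. The marker lists were fixed before the data were examined. The glutamatergic forebrain list had a median TPM of 73.9 ± 0.933, with all 10 members at 1 or more in both libraries. It was led by Camk2a, the synaptic calcium kinase, at 699 ± 116, by the calmodulin-binding protein Nrgn at 671 ± 63.7 and by the vesicular glutamate transporter Slc17a7 at 549 ± 99.04. CA1 pyramidal markers had a median of 28.5 ± 3.58 with 9 of 9 detected. Ccn3 led at 86.1 ± 3.20 and Mpped1 followed at 73.5 ± 5.66, with Fibcd1 at 44.5 ± 9.87 and Wfs1 at 38.8 ± 1.94. CA3 markers had a median of 28.3 ± 4.73 with all 8 detected, and the synaptic pentraxin Nptx1 stood at 78.7 ± 20.9. Dentate granule cell markers had a median of 12.3 ± 3.32 with all 10 detected, led by the granule cell transcription factor Prox1 at 42.4 ± 3.56 and the calcium buffer Calb1 at 40.1 ± 6.63. CA2 markers had a median of 8.44 ± 0.792 with 6 of 8 detected, led by Pcp4 at 113 ± 5.25 and Necab2 at 56.2 ± 9.13.

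Interneuron markers had a median TPM of 30.01 ± 2.44 and all 14 were detected. The peptide genes Cck at 231 ± 24.5 and Sst at 204 ± 1.19 led, ahead of Gad1, which makes GABA, at 95.3 ± 18.1 and the cannabinoid receptor Cnr1 at 81.7 ± 8.36. Cajal-Retzius markers had a median of 2.17 ± 0.134 with 4 of 7 detected. Calb2 at 50.6 ± 0.134 and the secreted guidance protein Reln at 46.4 ± 3.92 were highest there, and both are also made by interneurons. Progenitor and cycling markers had a median of 7.20 ± 1.27 with 12 of 13 detected. Dcx, a microtubule protein of immature neurons, led at 58.4 ± 15.2, followed by Hopx at 36.4 ± 3.72 and Sox11 at 26.6 ± 4.57.

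Astrocyte markers had the highest median of the cell type lists with all members counted, at 98.9 ± 2.02, with all 12 detected. With only members at a TPM of 1 or more, the red cell list was higher, at 268. Slc1a2, the main glutamate uptake carrier, stood at 704 ± 83.3, Slc1a3 at 204 ± 4.12 and Aldoc at 184 ± 14.3. Oligodendrocyte precursor markers had a median of 17.1 ± 0.824, led by the lineage factor Olig1 at 80.9 ± 6.74 and the growth factor receptor Pdgfra at 41.1 ± 0.156. Myelinating oligodendrocyte markers stood apart between the libraries, with medians of 6.91 and 23.2. Microglial markers had a median of 14.1 ± 0.325, and its members included Csf1r, a growth factor receptor, at 34.3 ± 8.27. Endothelial markers had a median of 11.8 ± 0.286, led by the tight junction gene Cldn5 at 44.4 ± 1.41 and the glucose carrier Slc2a1 at 25.3 ± 2.72. Pericyte and smooth muscle markers had a median of 6.47 ± 1.22 and meningeal fibroblast markers 6.62 ± 0.806, with Rgs5 at 46.5 ± 1.94 and Igf2 at 84.9 ± 9.64.

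Genes of the lists for neighbouring tissue were present. Whether they came from neighbouring tissue or from cells of the hippocampus was not tested. The thalamus and habenula list had a median of 6.48 ± 0.283 with 8 of 11 detected, led by Slc17a6 at 25.2 and 14.0. The neocortex and subiculum list had medians of 20.6 and 9.60, led by Fn1 at 57.0 and 36.3 and Etv1 at 31.8 and 28.6. The median log2 ratio of its members, replicate 2 over replicate 1, was only −0.11, within the range of matched random lists. The striatal list had a median of 2.18 ± 0.184, led by Ppp1r1b at 11.6 ± 1.44. Choroid plexus markers had a median of 2.27 ± 0.410, yet Ttr, the thyroid hormone carrier of that epithelium, stood at 422 and 670.1. The next member, Folr1, stood at 7.61 ± 0.141. Ependymal markers had a median of 2.23 ± 0.516, led by Mia at 6.07 ± 0.0212 and Rsph1 at 6.07 ± 0.417. Red blood cell transcripts were present, with a list median of 40.4 ± 3.37. Hbb-bs stood at 342 ± 12.7, Hba-a2 at 324 ± 29.95 and Hba-a1 at 268 ± 33.8, and the globin copies share reads. In the read-based table the list medians were 1.11 to 3.40 times as high, leaving out the list of RNAs without tails, which stood at 0.458 times, and the sex-linked list. The plot of list levels shows the libraries side by side.

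**Figure D1:**
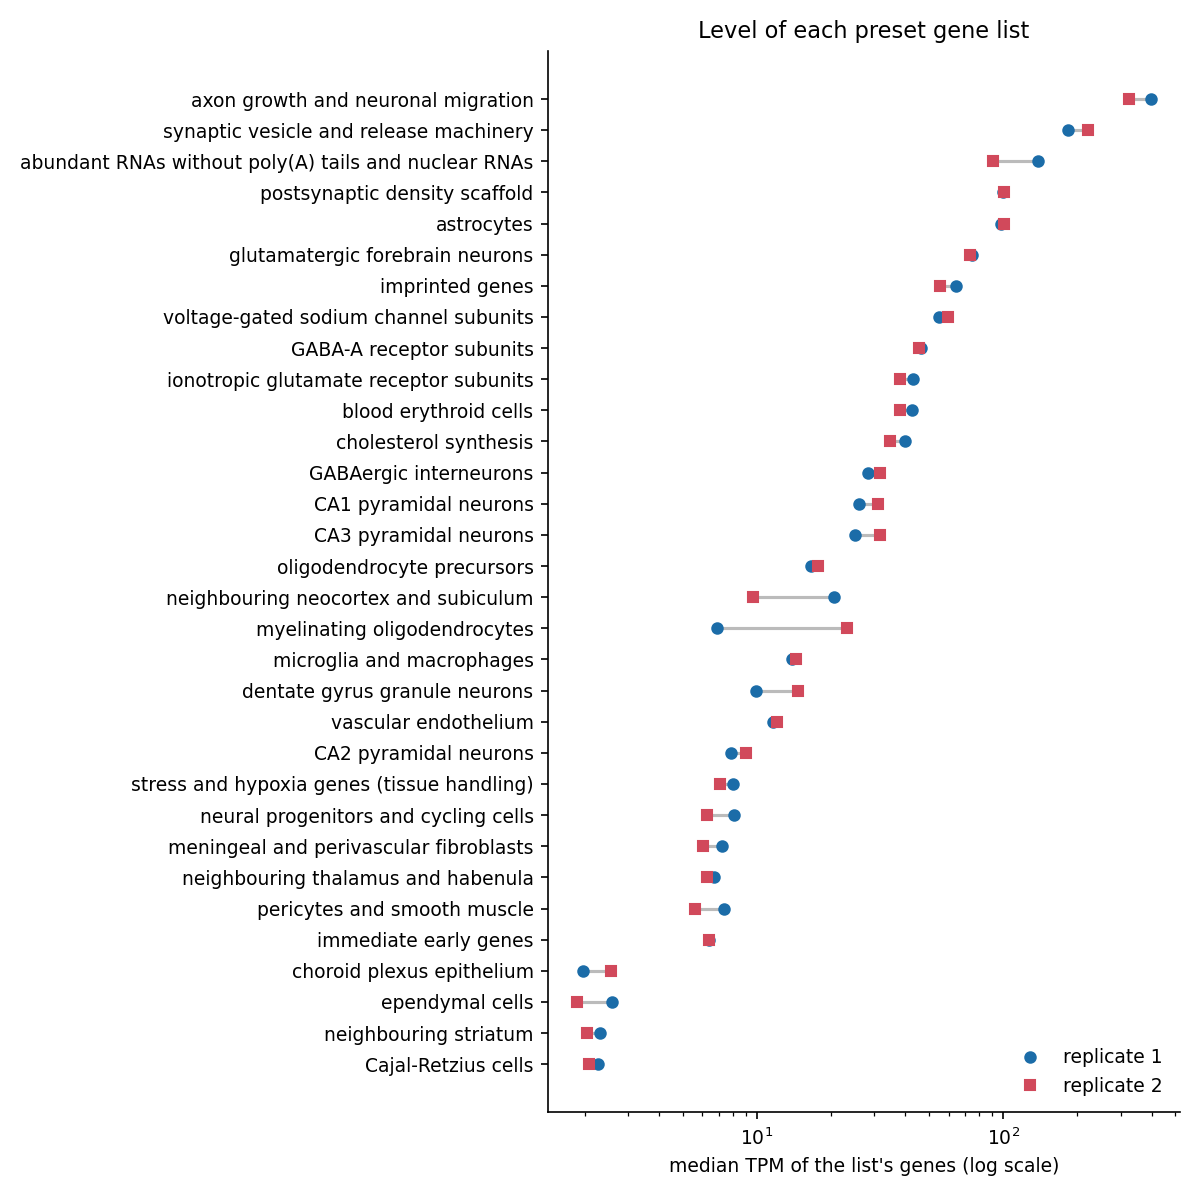
Median TPM of the genes of each preset list except the sex-linked one, on a log scale, with a circle for replicate 1 and a square for replicate 2. The largest gap among the cell type lists is that of myelinating oligodendrocytes, at 6.91 and 23.2.

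The third question was how far synaptic, receptor and growth programmes were expressed. Axon growth and neuronal migration genes had the highest median of all lists at 361 ± 51.6, ahead of the release machinery at 202 ± 27.0. Stmn2 and Tubb2b, which serve microtubules in growing axons, stood at 587 ± 92.9 and 549 ± 112, with Nnat at 543 ± 28.3 and Basp1 at 514 ± 29.4. The vesicle protein Syp at 711 ± 106, the fusion proteins Snap25 at 489.6 ± 19.5 and Vamp2 at 413 ± 20.8, and Cplx2 at 312 ± 16.2 led the release list. Postsynaptic scaffold genes had a median of 100.2 ± 1.26, led after Camk2a by Camk2b at 373 ± 27.1 and Dlg4 at 315 ± 9.31. Ionotropic glutamate receptor subunits had a median of 40.7 ± 3.48 with all 15 detected, led by Gria2 at 223 ± 14.6, Gria1 at 209.9 ± 14.7, Grin1 at 158 ± 9.40 and Grin2b at 145 ± 6.01. GABA-A receptor subunits had a median of 45.8 ± 0.661, and its members included Gabra5 at 91.3 ± 4.95. Sodium channel subunits had a median of 57.2 ± 3.53, and its members included Scn2a at 111 ± 4.34 and Scn3b at 92.9 ± 1.94.

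Immediate early genes, which respond to neuronal activity, had a median of 6.38 ± 0.0247, led by Egr1 at 20.6 ± 3.36, Junb at 16.3 ± 1.81, Nr4a1 at 15.1 ± 0.431 and Arc at 11.5 ± 0.813. Stress and hypoxia genes had a median of 7.54 ± 0.615, and Hsp90aa1, a chaperone, led at 449 ± 20.7, with Vegfa at 39.0 ± 4.97 and Ddit4 at 33.2 ± 1.43. Cholesterol synthesis genes had a median of 37.4 ± 3.62, led by Hmgcs1 at 264 ± 21.5, with Fdps at 67.7 ± 4.74. Imprinted genes had a median of 59.8 ± 6.27, led by the maternally expressed non-coding RNAs Meg3 at 1448 ± 269 (chromosome 12, 109541001 to 109571726) and Rian at 787 ± 103. RNAs without poly(A) tails and nuclear RNAs had a median of 114 ± 33.1, and Malat1, a nuclear speckle RNA, stood at 3297 ± 577. In the alignment-based table the sex-linked genes followed the female label. Xist, the RNA that silences an X chromosome, stood at 101 ± 19.8, and its antisense Tsix at 0.74 and 0.39, which is uncertain because use of strand in counting is not given in the sources used here. Ddx3y held 1 and 0 counts, Uty 0 and 2, and Eif2s3y and Kdm5d 0 in both libraries. The read-based table departed from this, with 123 and 93.1 estimated counts of Uty and 132 and 89.5 of Kdm5d, although Ddx3y held 8.02 and 4.14 and Eif2s3y 4 and 0.

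The fourth question was how paired genes stood to each other within each library. Adult-side members were ahead in some developmental pairs, while Grin2b, Scn2a and Sst, the juvenile-side members of their pairs, were ahead in others. Of 20 pairs fixed in advance, 17 had the same sign in both libraries and a mean beyond 2 SD, 13 with the first gene higher and 4 with the second. With 2 libraries the smallest two-sided p of an exact sign-flip test is 0.5, so no pair carries a test result. Values are log2 ratios, mean ± SD (n = 2), and are given for part of the pairs. Slc12a5, which exports chloride in mature neurons, exceeded Slc12a2, which imports it, by 3.16 ± 0.14, or 8.95-fold. Grin2b exceeded Grin2a by 0.68 ± 0.23, and this call was lost in the read-based table, where the mean was 0.34. Scaffold gene Dlg4, the adult-side member, exceeded Dlg3 by 2.42 ± 0.01. Scn2a, the juvenile-side member, exceeded Scn8a by 0.54 ± 0.04, and by 0.53 in the read-based table. Camk2a exceeded Camk2b by 0.90 ± 0.14 and the neuronal enolase Eno2 exceeded Eno1 by 0.58 ± 0.02.

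In the cell class pairs, Slc17a7 exceeded Slc17a6, the transporter of thalamic and subicular neurons, by 4.85 ± 0.86, with 4.24 in replicate 1 and 5.45 in replicate 2. It exceeded Gad1 by 2.53 ± 0.01. Sst exceeded Pvalb, the calcium buffer of fast-spiking interneurons, by 5.39 ± 0.91, with 6.03 and 4.74 in the libraries. Slc1a2 exceeded Slc1a3 by 1.78 ± 0.14 and Dcx exceeded the intermediate progenitor gene Eomes by 4.55 ± 0.44. Gfap exceeded Gja1, with a ratio of −0.38 ± 0.02 for Gja1 over Gfap. Xist exceeded Ddx3y by 9.84 ± 0.10, a size set by the 0.1 TPM added to each gene. Mbp over Pdgfra at 1.79 ± 1.16, Gria2 over Gria1 at 0.09 ± 0.20 and Prox1 over Wfs1 at 0.13 ± 0.19 did not reach 2 SD of the libraries.

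The fifth question was how closely the replicate pools matched. Most genes were close, and the genes of myelin formed the preset list with the largest shift. Across 16456 genes at a TPM of 1 or more in a library, Pearson r of log2(TPM + 1) was 0.982 and Spearman rho 0.983. Across 13462 nuclear protein-coding genes both were 0.991. These are correlations across genes, which are not independent replicates. Of 12072 protein-coding genes with 200 or more counts, 98.3% lay within 1.5-fold, and the SD of their log2 ratio was 0.23. The common biological coefficient of variation was 11.1% over 17903 genes.

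Myelin genes were higher in replicate 2. Mobp, a structural protein of compact myelin (ENSMUSG00000032517.16, chromosome 9, 120149707 to 120181484), stood at 7.08 and 39.1 TPM, a log2 ratio of 2.32 ± 0.08 (counting SE). Mbp, the main protein that compacts myelin (ENSMUSG00000041607.17, chromosome 18, 82475146 to 82585637), stood at 80.5 and 253. Of the 12 myelinating oligodendrocyte markers, 11 were higher in replicate 2 and 10 were called in that direction, also 10 when adjusted over the list alone. The list median was 1.59, or 3.01-fold, against −0.13 to 0.15 for the central 95% of random lists of the same size and level. Under TMM scaling the 10 precursor markers were also all higher in replicate 2, but by a median of 0.23. None was called, although 8 had an adjusted p under 0.05 by the exact test. Pdgfra stood at 41.0 and 41.2.

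The test behind these calls was an exact two-sided binomial test of the 2 libraries, which compares libraries and not conditions and has no replicate check. Of 20544 genes tested, 5467 had an adjusted p under 0.05, and 584 also differed by a log2 ratio of 1 or more. Of these, 115 were higher in replicate 2 and 469 higher in replicate 1, while without the ratio threshold 2981 were higher in replicate 2 and 2486 in replicate 1. Long non-coding genes gave 289, of which 280 were higher in replicate 1, and nuclear protein-coding genes gave 194, of which 70 were higher in replicate 2 and 124 in replicate 1. Both tables called 283 genes in the same direction. Scaling to spike-ins raised the count to 1276, with 88 higher in replicate 2 and 1188 higher in replicate 1. That scaling moved the median protein-coding log2 ratio from 0.03 to −0.25, so differences of lists and gene classes are reported relative to genes of the same level. Calls and ratios of single genes rest on TMM scaling without such matching.

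Of the 49 called genes with a mean TPM of 5 or more, 24 were higher in replicate 2 and 25 in replicate 1, so the excess toward replicate 1 was absent there, and 23 were called in both tables. The 10 with the largest ratio toward replicate 2 included several myelin genes. Beside Mobp, these included Mog at 2.11 ± 0.21, Mag at 1.81 ± 0.07 and Cldn11 at 1.66 ± 0.08. The adjusted p was 4.54e-220 for Mobp and 1.38e-28 for Mog by the exact test. Also among the 10 were the pseudogenes Gm6565, Gm6851, Gm28439, Gm10145 and Gm16199, uncertain because reads can be shared with parent genes. Gm6565 held 0 and 232 counts, at least 75.04-fold higher in replicate 2 with a floor of 3 counts, and Gm6851 was at least 23.0-fold higher.

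Toward replicate 1, Tshz2, a zinc finger transcription factor (ENSMUSG00000047907.11, chromosome 2, 169633013 to 170071816), stood at 28.4 and 6.79, a log2 ratio of −1.88 ± 0.06. Rxfp1, the receptor of relaxin (chromosome 3, 79641611 to 79737880), stood at 16.7 and 4.36, a ratio of −1.82 ± 0.07. Pagr1a had a ratio of −2.20 ± 0.18 that moved to −9.07 in the read-based table, so it is uncertain. Hist1h2ao, a histone gene with near-identical copies, was at least 42.9-fold lower in replicate 2 and Gm10222, in the same region of chromosome 1 as Gm28661, at least 29.2-fold lower. The others were Mir1949, Gm24616, Gm10443, Gm10335 and Gm22154, small RNAs and pseudogenes with ratios from −2.15 to −1.35. Of all 20 genes, 10 were under the count minimum in the read-based table, and Gm10335 lost its call there.

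Several other groups shifted by small amounts relative to genes of the same level. Of the 33 preset lists, 16 had a median ratio outside the 95% range of matched random lists, 10 above and 6 below, where 1.65 would fall outside if genes and lists were independent. Genes of a list can vary together and some lists share genes, so more than that can fall outside without a shift of the tissue. Above the range, beside the myelin and precursor lists, were dentate granule markers at 0.36, with 10 of 10 higher in replicate 2, CA2 markers at 0.37, choroid plexus markers at 0.45, interneuron markers at 0.24 and CA3 markers at 0.19. Release machinery genes at 0.21, with 15 of 16 higher, immediate early genes at 0.20 and astrocyte markers at 0.19 were above it too. Counts of members higher or lower hold for TMM scaling alone, since spike-in scaling lowers all ratios. Below the range were axon growth and migration genes at −0.23, with 13 of 15 lower, and progenitor and cycling markers at −0.26, with 9 of 13 lower. Cholesterol synthesis at −0.05 also lay below. So did thalamic markers at −0.33, which returned inside the range with 50 or more counts per member at −0.14. Imprinted genes at −0.03 and RNAs without tails at −0.17 were inside the range in the read-based table.

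Few members of these lists were called, since a call also needs a log2 ratio of 1 or more. Many had an adjusted p under 0.05 by the exact test at smaller ratios. Among them were 15 of 16 release machinery genes, 13 of 15 axon growth genes and 8 of 10 dentate granule markers. Such a p is common at high counts: 37.3% of the 11071 tested genes with a mean TPM of 5 or more had it. The share at the level of each list was not computed, so these counts partly reflect depth. Pvalb was the interneuron marker that was called, at 3.00 and 7.54 TPM. In the neocortex and subiculum list, whose median of −0.11 stayed within its range, 3 genes were called higher in replicate 1, which were Tshz2, Nts and Foxp2. The 1 thalamic gene was Gbx2, the 1 red cell gene Slc4a1, the 1 immediate early gene Fosb and the 1 nuclear RNA gene Rmst. The 2 imprinted genes were H19, higher in replicate 1, and Dlk1, higher in replicate 2. Foxp2, Nts and the genes from Gbx2 to Dlk1 were chosen after their values were seen. Each of these counts was the same when adjusted over the list alone. The remaining lists, apart from the myelin list, had 0 genes called by the exact test with the ratio threshold at both adjustments. CA1 and glutamatergic forebrain markers, receptor and channel subunits, scaffold genes, vascular and mural cells, meninges, ependyma, striatum, blood, stress genes and the 2 sex-linked genes with enough counts had medians within their ranges. So had microglia at 0.10 and Cajal-Retzius markers at −0.04, although microglial and mural markers moved above the range in the read-based table, at the 99.03 and 98.6 percentile.

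**Figure D2:**
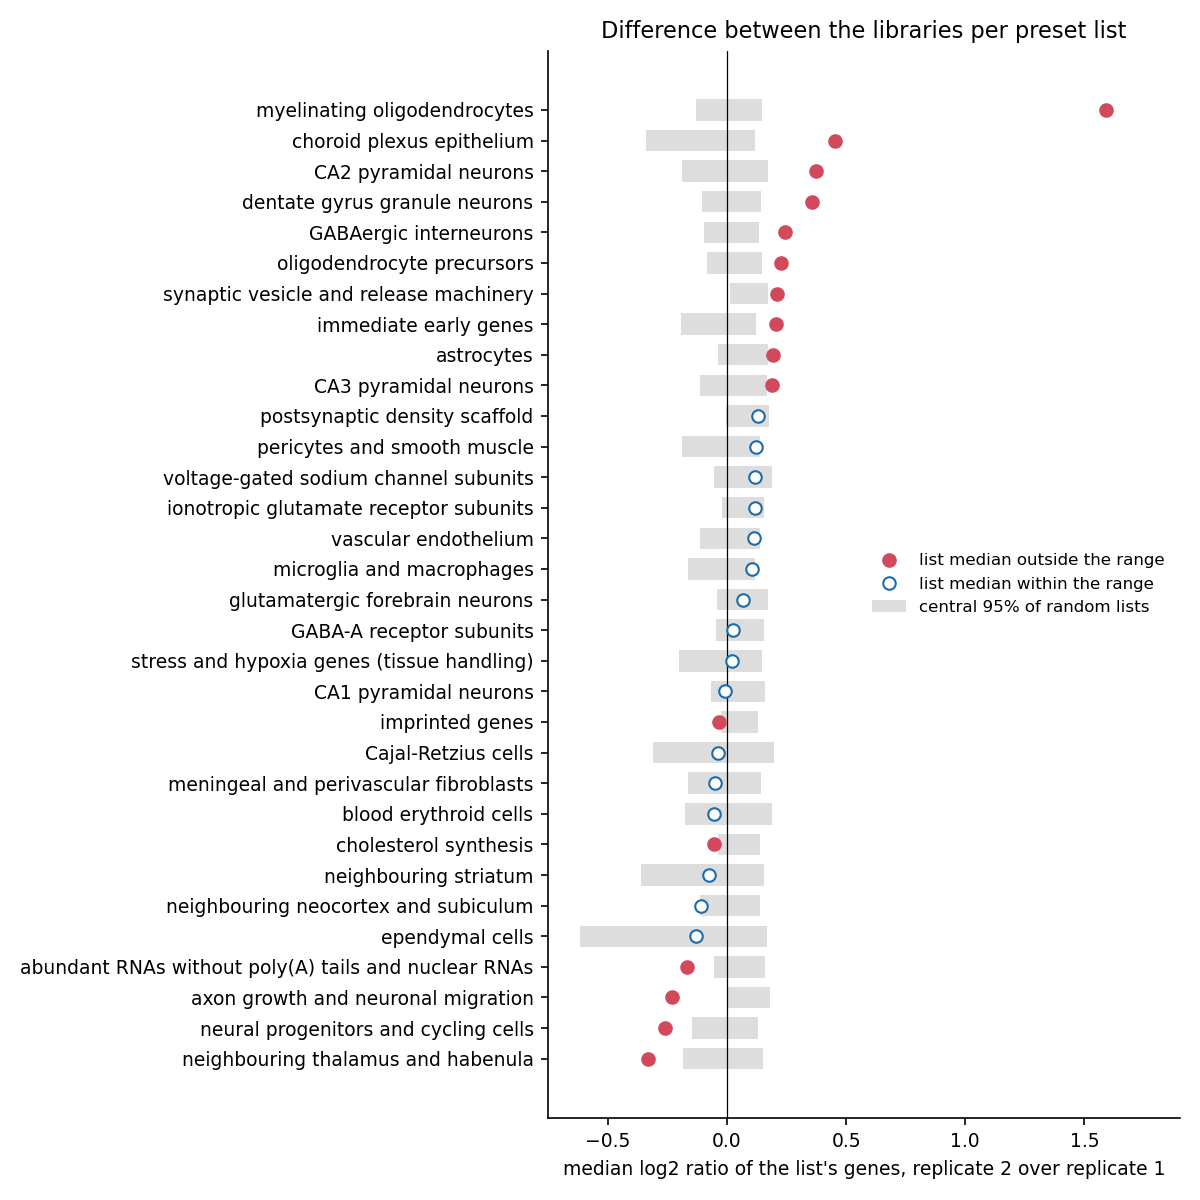
Median log2 ratio of replicate 2 over replicate 1 of each preset list except the sex-linked one, with a bar for the central 95% of the medians of 10000 random lists of the same size and level. Filled points lie outside that range, and myelinating oligodendrocytes lie farthest at 1.59.

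Several non-coding classes were higher in replicate 1. Of 218 genes of the annotation class TEC, single-exon transcripts still to be tested, 200 were higher in replicate 1, with a median log2 ratio of −0.55. The 25 sense-intronic genes had a median of −0.53, the 133 long intergenic genes −0.25 and the 77 genes of the class of processed transcripts −0.13. The 48 antisense genes, at −0.07, lay within the range of matched protein-coding lists. The 199 processed pseudogenes, at 0.07, and 21 small nucleolar RNAs, at 0.11, lay above their ranges. In the read-based table both class medians were −0.01, the value that a gene with 0 counts in both libraries takes there, so they do not measure a shift. Sense-intronic and TEC genes can overlap introns of other genes, so their counts are uncertain. Transcripts annotated with a retained intron made up 5.08% of the summed counts of retained-intron and coding transcripts in replicate 1 and 4.02% in replicate 2.

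The last question was which transcripts the genes used and whether the 2 quantifications of each library gave the same ones. Neuronal genes kept 1 leading transcript in both libraries, while the tables named different leading transcripts for part of the genes. Of 20 genes fixed in advance, all 20 had the same leading transcript in both libraries by the alignment-based table and 18 by the read-based table, and 15 had the same one in both tables. Syt1, the calcium sensor of release, used Syt1-201 for 87.7 ± 0.50% of its TPM, and Mapt, which encodes tau, used Mapt-204 for 84.0 ± 2.19%. Snap25-201 held 71.6 ± 2.57%, Clta-205 held 63.0 ± 5.45% and Gria2-202 held 55.2 ± 1.83%. Smaller leading shares were those of Pkm-201 at 48.9%, Grin1-201 at 43.2%, Map2-204 at 39.6%, Ntrk2-201 at 31.8% and Ank3-244 at 21.3%. Bdnf, Mbp, Dlg4 and Meg3 were among the genes that had different leading transcripts in the tables. Mbp-211 led with 48.4 ± 7.56% in the alignment-based table, where the read-based table gave it 15.0%. Across 9535 genes, the tables named the same leading transcript for 75.5% in replicate 1 and 75.1% in replicate 2, and the libraries shared it for 90.6% by alignment and 86.7% by reads. The rank correlation of the tables across transcripts was 0.522 in replicate 1 and 0.519 in replicate 2. Across protein-coding genes it was 0.979 and 0.980.

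Spike-ins, whose sequences have no genomic copies, were counted lower in the read-based table. For 26 spike-ins with 50 or more counts in both libraries, the ratio of read-based to alignment-based counts ran from 0.329 to 0.917 in replicate 1 and from 0.341 to 0.914 in replicate 2. The ratio was higher for longer spike-ins, with a rank correlation of 0.798 and 0.753 across spike-ins. Transcripts of 200 bases or more but shorter than about the fragment length of the read-based table held 29.0% and 30.6% of the alignment-based TPM, and their count ratio was 0.000506 and 0.0054.

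**Figure D3:**
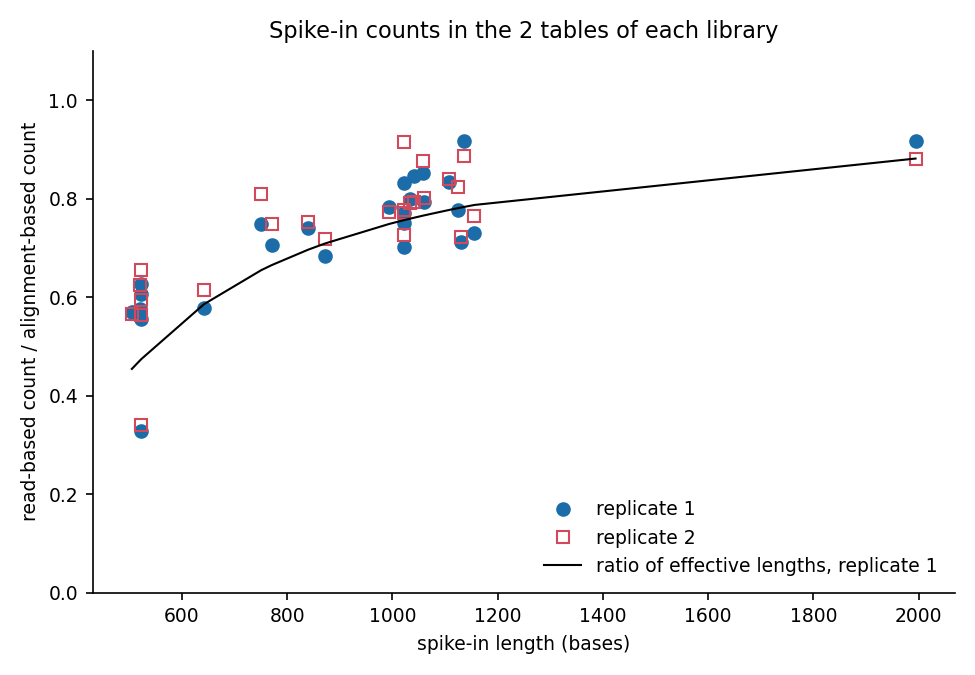
Ratio of read-based to alignment-based counts of 26 spike-ins against spike-in length in bases, with circles for replicate 1, squares for replicate 2 and a line for the ratio of the effective lengths of replicate 1. The lowest ratio is 0.329 and the highest 0.917.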

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

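All tests of explanations in this part were chosen after the results were seen, except the test of genomic DNA, which was written before its result was seen. Y-linked genes had signal in the table that the main comparisons did not use. In the read-based table Uty held 123 estimated counts in replicate 1 and 93.1 in replicate 2, and Kdm5d held 132 and 89.5. Ddx3y held 8.02 and 4.14, and Eif2s3y 4 in replicate 1 and 0 in replicate 2. All but the last lay above the 3 counts that a count of 0 allows. In the alignment-based table Uty held 0 and 2 counts and Kdm5d 0 in both. Over 183 Y-linked genes the alignment-based tables held 7 counts each, against 2900 and 1808 estimated counts by the read-based quantification. Both libraries were labelled female.

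Myelin genes were higher in replicate 2, with a list median of 1.59 on the log2 scale. More thalamus or neocortex in replicate 2 would raise markers of either region, but the higher of their 2 list medians was −0.11. A larger share of the whole oligodendrocyte lineage would move precursor genes by as much, but the upper quartile of the precursor list was 0.39, under the lower quartile of 1.16 of the myelin list. A later stage of maturation in replicate 2 stays open. The medians of the growth and cycling lists lay below their random ranges, at −0.23 and −0.26, with 0 genes of either list called at a log2 ratio of 1 or more. By the exact test at an adjusted p under 0.05, 12 of 15 growth genes were lower in replicate 2 and 1 was higher. Of 13 cycling genes, 8 were lower and 2 higher in the same way. Of all tested genes with a mean TPM of 5 or more, 37.3% had an adjusted p under 0.05 by that test in either direction. Of 9 developmental gene pairs, 6 moved to the adult side, too few to decide. More white matter in the dissected tissue could also account for the pattern and was not tested, and the design gave no biological group against which to test it.

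Unspliced and intronic gene classes were higher in replicate 1, with a median log2 ratio of −0.55 for single-exon TEC transcripts. A trend with expression level is argued against as the whole cause, since protein-coding lists of the same level had a median of −0.0493. More genomic DNA in replicate 1 stays open in part. Odorant and vomeronasal receptor genes, silent in brain, summed to 817 and 741 counts, a ratio of −0.18 with an interval of −0.33 to −0.04. This fell short of the limit written beforehand and of the −0.55 of the TEC class, but the interval lay below 0. Receptor counts that do not come from DNA would also hide part of a difference. More unspliced RNA in replicate 1 may account for the higher classes. Within 5146 genes, the ratio of retained-intron to coding transcripts was lower in replicate 2 by a median log2 difference of −0.39, with a bootstrap interval of −0.41 to −0.37. Reads of genomic DNA in introns would act in the same direction, so this does not separate unspliced RNA from DNA. The bootstrap interval covers the spread among genes of these 2 libraries and not the spread between pools. Whether the retained-intron difference came from the tissue or from the extraction was not tested, and no biological explanation was tested because the design has 1 group.

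Short RNAs as a class were nearly missing from the read-based table. Loss of reads to near-identical copies stays open for the short RNAs, since the spike-ins that could test it were longer. Counts can fall without it: all 26 spike-ins with 50 or more counts in both libraries, which have no copies, fell below their alignment-based counts. Their ratios ran from 0.329 to 0.917 in replicate 1, and the lowest was 1 spike-in apart from others of its length. Loss of reads near transcript ends under an assumed fragment length may account for the lower counts of the longer spike-ins, and stays open for the short RNAs. The effective lengths correspond to a fragment of 325.02 and 317 bases in the read-based tables and 100 in the alignment-based ones. The ratios of the 26 spike-ins lay a median of 0.0786 on the log2 scale from what those lengths predict in the library farther from 0. The shortest of these 26 had 505 bases, so they do not decide it for shorter RNAs. The spike-in ERCC-00051, of 274 bases, had 20 and 21 alignment-based counts and 0 and 0 read-based ones. For it the lengths predict ratios of 0.300 and 0.275. Rpph1 and Rn7sk are annotated at about the fragment length of the read-based tables. Rpph1 held 7 and 6636 read-based counts, against 39807 and 46845 alignment-based ones. Rn7sk held 22 and 334, against 306864 and 335269. Both kept a larger share in replicate 2, where the fragment was shorter, but these genes alone do not decide the cause. No biological explanation was tested, since both tables came from the same libraries.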

How the results depend on the processing

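All alternatives were chosen before the data were examined, except the count of genes called in both tables. No paired analysis was possible because the series has 1 group and no contrast between groups. No called pair and no named differing gene with a value changed sign, and no list moved from 1 side of its random range to the other. Detected protein-coding genes ran from 10144 to 13880 over the TPM thresholds and tables, and from 13161 to 13320 without either replicate. Of the 20 pairs, 16 to 17 were called, and of the 33 lists 15 to 16 lay outside their random range. Of the pairs, 19 stayed on the same side of the call in the read-based table and 1, Grin2b over Grin2a, was weaker, and all 20 stayed with other pseudocounts and with FPKM, which scales both genes of a pair alike. A single library gives no SD, so leaving out a replicate was no test of the pair calls. The pairs Gria2 over Gria1 and Prox1 over Wfs1, neither of them called, changed sign between the libraries. List shifts stayed on the same side for 29 lists in the read-based table, with 2 stronger and 2 weaker, and for 32 with members of 50 or more counts, with 1 weaker. List levels moved by more than the spread between libraries for 33 lists with protein-coding genes alone, 31 in the read-based table and 9 with members at a TPM of 1 or more. With protein-coding genes alone, all levels of a library are divided by the same total, so this was no test of the levels. In the read-based table short RNAs held 0.465% of the TPM against 38.1%, and protein-coding genes 75.1% against 44.8%, which raises other levels within a fixed total. Causes beyond this were not tested. The 9 follow from leaving out members at low levels. Leaving out a library moves a mean of 2 by less than 1 SD whatever the values, so it was no test of the levels. The order of the cell type lists changed with the setting. The red cell list had a median of 268 with members at a TPM of 1 or more, above astrocytes at 98.9. In the read-based table it stood at 137, above glutamatergic neurons at 112. Calls of named differing genes held for 17 with 50 counts, where Mir1949, Gm24616 and Gm22154 gave no value, and for 9 in the read-based table, where 1, Gm10335, was weaker and 10 gave no value. Other scalings move all genes alike, by too little to end these calls or to move lists against random lists, so they were no test of either. The correlation of the replicates was 0.952 with a pseudocount of 0.1, 0.993 with no filter, 0.978 at a TPM of 5 or more and 0.982 in the read-based table. The count of genes differing between the libraries, 584, became 1276 with spike-in scaling (88 higher in replicate 2, or 6.90% against 19.7%), 313 with 50 counts, 1184 at a threshold of 1.5-fold, 5467 with no ratio threshold (2981 higher in replicate 2, or 54.5%, so the excess of 469 against 115 toward replicate 1 became 2486 against 2981), 201 with protein-coding genes alone (70 higher in replicate 2, or 34.8%) and 283 in both tables. With protein-coding genes alone the scaling was fitted again as well, and the same genes gave 194 under the main scaling, so 2 choices changed at once. The cause of the change with spike-ins was not tested. The counts at other thresholds and in both tables follow from looser and stricter conditions. DESeq2 size factors gave 586, total counts 666, no filter 564 and the read-based quantification 737, of which 283 were shared with the main count. The coefficient of variation of 11.1% became 11.2% with DESeq2 size factors, 11.7% with no filter, 9.38% with protein-coding genes alone and 12.6% in the read-based table, and the cause was not tested. The share of genes with the same leading transcript in both tables, 75.3%, became 74.6% at a gene TPM of 1 and 74.7% at 20. Protein-coding genes held 79.4% of counts against 44.8% of TPM, which follows from the division by length. The leading transcript was the same in both libraries for 18 of 20 isoform genes in the read-based table. Depth limited the call of genes with few counts, and 2 pools gave no estimate of variation between single animals.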

Other observations

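The gene groups in this part were chosen after the data were examined. Genes of the extracellular matrix around neurons differed widely in level. The proteoglycans Ncan and Bcan stood at a TPM of 253 and 240.0 and of 175 and 188 in replicates 1 and 2, and the cross-linking protein Tnr at 49.6 and 62.1. Acan, the proteoglycan of mature perineuronal nets, stood at 2.48 and 3.03 and Hapln4 at 3.35 and 5.01, while Hapln1 stood at 36.5 and 35.5. Among hormone receptors, the thyroid hormone receptor Thra led at 583 and 584, followed by the mineralocorticoid receptor Nr3c2 at 43.5 and 47.6 and the glucocorticoid receptor Nr3c1 at 24.0 and 26.9. The progesterone receptor Pgr stood at 4.08 and 4.03 and the oestrogen receptor Esr1 at 0.96 and 0.43.

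Neurotrophin receptors Ntrk2 at 117 and 119.7 and Ntrk3 at 87.2 and 80.2 were far above the neurotrophins Bdnf at 11.9 and 14.8 and Ntf3 at 5.04 and 5.12. Among neuropeptides other than Cck and Sst, Npy stood at 36.8 and 41.4, Penk at 7.27 and 8.94, Tac1 at 7.10 and 7.61 and Vip at 3.97 and 3.71. Adcyap1 stood at 9.32 and 5.48. The 39 Hox genes, which pattern hindbrain and spinal cord, held 8 and 2 counts in all, and the highest mean TPM among them was 0.05.

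Mitochondrial messenger RNAs differed in direction between the libraries. The levels of mt-Co3 were 744 and 1233 and those of mt-Nd4 2047 and 1366, with log2 ratios of 0.82 and −0.49. Reads of mitochondrial genes may be shared with a region of chromosome 1 known as a nuclear copy of mitochondrial DNA, which was not matched by sequence here and where Gm28439 held 46 and 5326 counts, and 3190 and 8431 estimated counts in the read-based table, so these levels are uncertain.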
